A study of Mus musculus with 32 samples.

How the data were processed

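Expression was measured on 32 Affymetrix arrays of mouse tumour-associated macrophages, 100 ng of RNA per array, in 12 groups taken from the labels. The HT_MG-430_PM chip carried 16 arrays of CD11b-enriched cells, and the Mouse Gene 2.0 ST chip carried 16 arrays of flow-sorted cells. The deposited values are log2 signals per probe set, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, puts the arrays on one distribution and summarises the probes of a probe set, so a global shift in RNA content between samples would be removed before any comparison. Which arrays were normalized together is not given in the sources used here. From the values, the 6 arrays of the tumour model experiment had medians of 3.84 to 3.93, the 10 arrays of the Myd88 experiment 2.95 to 3.03, and the 16 sorted arrays 5.31 to 5.5. The first 2 sets were therefore tested apart, and differences across them are reported only as a measure of the gap between experiments. No counts or depth exist for arrays, so the number of arrays limits the precision.

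Probe sets were named from the platform annotation. On the HT_MG-430_PM chip 28898 of 45141 probe sets had 1 gene symbol, 551 had several and 15692 had none, and 28689 matched the gene table of assembly GRCm38.p6 by Entrez identifier. On the Mouse Gene 2.0 ST chip 23521 of 41345 probe sets had 1 symbol, 1814 had several and 16010 had none, and 23328 matched. Each gene was represented by its probe set of highest mean over the arrays of the chip, which left 17097 and 22180 genes. Genes were tested when their value lay above the 40th percentile of the probe sets of an array in at least as many arrays as the smallest group compared. Positions were used only to find which genes neighbour the targeted genes, and no coordinates are given because the build behind the annotation is not stated.

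Groups were compared on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. On the HT_MG-430_PM chip each fit held only the arrays of the 2 groups compared. The sorted arrays were fitted together as 8 groups of 2, with 8 residual degrees of freedom, and contrasts gave A against C in WT hosts, each genotype against WT in A and in C, the double knockout against each single one averaged over A and C, the departure of the double effect from the sum of the single effects, and the difference of each genotype effect between A and C. Values after ± are standard errors of the log2 difference unless named otherwise.

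The report names, per comparison, Myd88 and Tnfrsf1a first. It then names the 10 genes with the largest rise and the 10 with the largest fall, among called genes whose groups did not overlap, for the main comparisons, and 5 and 5 for the others. From each gene list it names up to 4 called members of smallest adjusted p, or 2 members of smallest p where none was called. Predicted genes without a name were counted only. This rule, the main tests, the gene lists and most of the other settings tried were fixed before the data were examined.

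The 25 gene lists were inflammatory cytokines and chemokines, NF-kB targets and feedback, alternative activation (IL-4/STAT6), type I interferon response, interferon-gamma response, MHC class II presentation, cell cycle, hypoxia and glycolysis, lipid and cholesterol handling, matrix remodelling and angiogenesis, TLR, IL-1R and TNFR pathway components, immediate-early and dissociation stress, red blood cell transcripts, sex-linked transcripts, and markers of monocytes, mature macrophages, dendritic cells, neutrophils, T lymphocytes with the EG7 line, B lymphocytes, natural killer cells, eosinophils with mast cells, neuroblastoma with sympathetic neurons, fibroblasts and endothelium. Each was tested in each contrast with camera of limma at a preset inter-gene correlation of 0.01, which compares the list with all other genes tested. The same test was repeated with the correlation estimated from the residuals, and fry tested whether the members moved on balance one way. P-values were adjusted over the 50 list tests of the HT_MG-430_PM chip and over the 350 of the sorted arrays. At the preset correlation 17 of the 50 and 159 of the 350 tests were called. With an estimated correlation 8 calls held in all, 1 on the first chip and 7 on the second, and these are named where they occur. Fry called 9 of the 50 and 38 of the 350 tests. The preset value assumes weakly correlated genes, so most list calls depend on that assumption.

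The gene fits of 8 comparisons, and camera at the preset correlation in them, were tested on simulated data with 200 changed genes drawn from the real means and spreads. Genes were simulated as independent, so the preset correlation itself was not tested, and the other comparisons, the estimated correlation and fry were not simulated. At a log2 difference of 1 the fit recovered 37% of the changed genes among 12577 for neuroblastoma against EG7, 95% among 11915 for Myd88-/- against WT, and among 16524 genes 69% for A against C, 77% for the double knockout in A, 74% in C and 26% for the difference of the double effect between A and C. At a log2 difference of 2 the recovered shares were 81%, 100%, 97%, 100%, 98% and 83%. No changed gene was called with the wrong sign (0 in each). Unchanged genes made up 3.3% to 7.6% of the calls, and the highest share, 16 genes for Myd88-/- against WT, lay above the adjustment's 0.05. Each simulation is 1 draw, and unequal spread, as in A_WT (array weight 0.331), was not tested.

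No array pair held identical values (0 pairs). The replicate numbers of the labels were checked as pairing by correlating the deviations of same-numbered arrays. Other settings tried were no filter or a filter at the 60th percentile, quantile normalization again, the mean of a gene's probe sets, eBayes with trend and robust settings, a 2-fold minimum, a replicate block, other sets of arrays in the fit, and each array left out in turn. Settings added after the data were seen were the level of Xist, or of the Y-linked Eif2s3y in the sorted arrays, as a covariate, fits within arrays of high or low Xist, array weights by group, crossed replicate numbers, and a separate WT array as the control of each genotype effect where effects were correlated. Glioma arrays that the design text mentions were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.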

Results

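Tumour-associated macrophages, the myeloid cells that settle in tumours, were profiled from mouse tumours on 32 arrays. In a first experiment, RNA came from CD11b-enriched cells of 2 tumour models, with 3 arrays each: neuroblastomas arising in Th-MYCN transgenic mice, and tumours grown from EG7, a transplantable thymoma line of T lymphocyte origin. A second experiment used CD11b-enriched cells of EG7 tumours grown in WT or Myd88-/- hosts, with 5 arrays each. Myd88 is the adaptor through which most Toll-like receptors and the receptors of the interleukin-1 family signal. In the last experiment, 2 populations were sorted by flow cytometry from EG7 tumours. Population A was positive for CD11b and Ly6C and negative for Ly6G and MHC class II, whereas population C was positive for CD11b and MHC class II and negative for Ly6C. Each was taken from WT hosts, from TNFR1-/- hosts that lack the tumour necrosis factor receptor encoded by Tnfrsf1a, from hosts with floxed Myd88 deleted by Tie2-Cre (Myd88 cKO), and from hosts with both changes (double KO), with 2 arrays per genotype and population. Correlations of an array with its own group were 0.973 to 0.99 in the tumour models, 0.992 to 0.994 in the Myd88 experiment and 0.931 to 0.987 in the sorted arrays, where the lowest value belonged to the A_WT pair. The labels do not say that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

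In EG7 tumours of WT hosts, the Myd88 log2 signal was 8.57, 8.37, 8.44, 8.37 and 8.11, against 7.6, 7.69, 7.53, 7.83 and 7.47 in Myd88-/- hosts, a difference of -0.75 ± 0.10 (n = 5 each, limma adjusted p = 0.00175). In the tumour models Myd88 read 9.25, 10.15 and 8.86 in neuroblastoma and 9.59, 9.72 and 9.28 in EG7. Among sorted arrays, Myd88 read 10.03 and 9.64 in A_WT, 9.68 and 9.46 in A_TNFR1KO, 7.84 and 7.7 in A_Myd88cKO, and 7.78 and 8.32 in A_doubleKO. In population C the values were 9.78 and 9.22 for WT, 9.72 and 10.05 for TNFR1-/-, 7.49 and 7.53 for Myd88 cKO, and 8.76 and 7.97 for double KO. All 8 arrays with the Myd88 deletion thus lay below all 8 without it, although the fall in double KO of population C, -1.13 ± 0.27, did not pass the test (adjusted p = 0.129).

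Tnfrsf1a moved less. Its log2 signal was 8.3 and 8.09 in A_WT, 7.51 and 7.59 in A_TNFR1KO, 7.95 and 8 in A_Myd88cKO, and 7.69 and 8.2 in A_doubleKO. In population C it was 8.55 and 7.81 for WT, 7.56 and 7.87 for TNFR1-/-, 8.43 and 8.04 for Myd88 cKO, and 7.55 and 7.7 for double KO. None of these differences from WT passed the test, with Tnfrsf1a at -0.64 ± 0.23 (adjusted p = 0.169) for TNFR1-/- in A and -0.47 ± 0.23 (adjusted p = 0.997) in C. Whether the probe set lies inside the deleted part of Tnfrsf1a is not given in the sources used here, so its level checks nothing certain about these labels. On the bead-enriched arrays Tnfrsf1a read 9.84, 9.7 and 9.4 in neuroblastoma, 9.58, 9.53 and 9.1 in EG7, 8.35, 8.17, 8.33, 8.22 and 8.16 in WT, and 8.46, 8.5, 8.29, 8.69 and 8.5 in Myd88-/- hosts.

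The first comparison asked how macrophage profiles differ between tumour models. CD11b-enriched cells of neuroblastomas carried high levels of genes of sympathetic neurons. Chgb, which encodes the granule protein chromogranin B, was higher by 7.26 ± 0.30 on the log2 scale (n = 3 each, limma adjusted p = 8.53e-05), Isl1, a transcription factor of sympathetic neurons, by 6.82 ± 0.35, and the neurofilament genes Nefl and Nefm by 6.64 ± 0.40 and 5.95 ± 0.43. Th and Ddc, enzymes of catecholamine synthesis, were higher by 5.00 ± 0.28 and 4.96 ± 0.25. The other largest rises were Agtr2 (7.43 ± 0.29), an angiotensin receptor, Umod (6.78 ± 0.50), Car3 (6.36 ± 0.23), Hal (6.09 ± 0.25), Ndn (5.93 ± 0.23) and the interferon-inducible Ifi202b (5.88 ± 0.36). Cells of EG7 tumours instead carried T lymphocyte genes. The T cell receptor chains Cd3d and Cd3g were lower in neuroblastoma at -5.59 ± 0.61 and -5.26 ± 0.56, the T cell adaptor Lat at -5.20 ± 0.32 and the thymocyte chemokine receptor Ccr9 at -4.96 ± 0.58. Further falls were Rhox5 (-6.77 ± 0.35), the tumour antigen gene Trap1a (-6.50 ± 0.13, adjusted p = 9.22e-06), the stromelysin Mmp3 (-6.20 ± 0.22), Perp (-6.16 ± 0.27), Mpp4 (-5.08 ± 0.25) and Slc6a13 (-5.00 ± 0.17).

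By list, 16 of 20 measured neuroblastoma and sympathetic neuron markers were higher and 0 lower (17 adjusted over the list alone), with a median of 4.05 and a camera adjusted p = 7.75e-15, or adjusted p = 0.457 with an estimated correlation. Of 17 T lymphocyte and EG7 line markers, 10 were lower and 1 higher (10 and 1 adjusted over the list alone, median -1.69, adjusted p = 7.34e-06), among them Bcl11b at -3.34 ± 0.33 and Thy1 at -2.03 ± 0.20. The list gave adjusted p = 0.611 with an estimated correlation. Endothelial markers were higher for 11 of 15 (14 adjusted over the list alone, median 1.52, adjusted p = 3.56e-08). With 1 array left out, 5 to 15 were higher. Kdr differed by 2.51 ± 0.22 and Emcn by 2.55 ± 0.24. That list call gave adjusted p = 0.611 with an estimated correlation. Fibroblast markers were higher for 5 of 14 (7 adjusted over the list alone, median 0.91, adjusted p = 0.00304), with Mgp at 4.24 ± 0.30 and Pdgfrb at 1.85 ± 0.31. This became adjusted p = 0.937 with an estimated correlation.

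**Figure D1:**
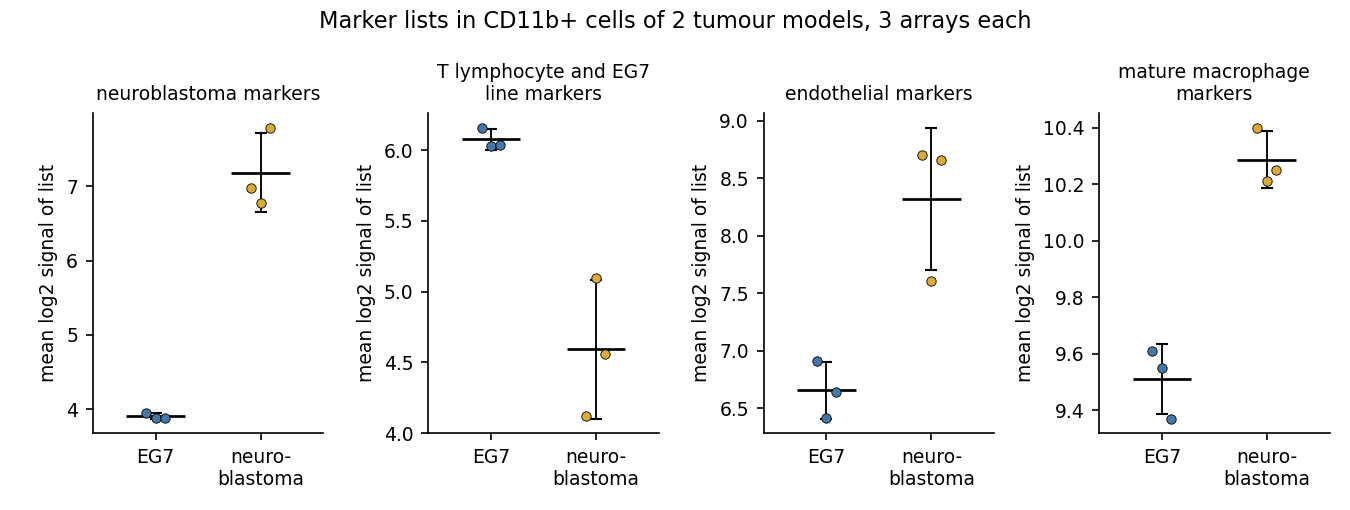
Mean log2 signal of 4 marker lists (y axis) in CD11b-enriched cells of EG7 tumours and neuroblastomas (x axis), 3 arrays each. Points are arrays, the horizontal line is the mean and the error bar is 1 SD. Neuroblastoma markers lie between 6.78 and 7.79 in neuroblastoma against 3.89 to 3.95 in EG7, and T lymphocyte and EG7 line markers between 4.12 and 5.1 against 6.03 to 6.16.

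Mature macrophage markers were higher for 5 of 24 and lower for 2 (8 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 0.0165, adjusted p = 0.683 with an estimated correlation). Timd4, a phosphatidylserine receptor of resident macrophages, was higher by 4.40 ± 0.54 and the fractalkine receptor Cx3cr1 by 1.5 ± 0.22, while Gpnmb was lower at -1.68 ± 0.17. Cadm1, also in this list, was higher by 5.35 ± 0.24 and encodes an adhesion molecule that neurons also express. Other lists did not pass the test as a whole but held single called genes. Of 16 MHC class II presentation genes, 2 were lower (3 adjusted over the list alone, adjusted p = 0.223), H2-Eb1 at -4.56 ± 0.62 and H2-Aa at -2.63 ± 0.48. The 29 alternative activation genes had 2 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.779), among them the chemokines Ccl24 at 2.36 ± 0.38 and Ccl17 at -2.12 ± 0.40. Of 18 lipid and cholesterol handling genes, 3 were higher and 2 lower (4 and 2 adjusted over the list alone, adjusted p = 0.49), with Apoc1 at 4.33 ± 0.37 and the desaturase Scd1 at 4.43 ± 0.49. The 5 red blood cell transcripts measured had 0 calls (0 adjusted over the list alone, median -0.11, adjusted p = 0.842), with Hba-a2 at -0.46 ± 0.17. Sex-linked transcripts were tested only through Xist, the transcript of the inactive X chromosome, at -1.52 ± 1.64 (adjusted p = 0.59).

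Several list results of this comparison depend on NB_model array 2, which was singled out after its values were seen. Its list means stood apart from those of NB_model arrays 1 and 3 for MHC class II presentation (10.3 against 8.71 and 9.28), interferon-gamma response (9.6 against 6.9 and 7.27), type I interferon response (9.16 against 6.08 and 6.82) and natural killer cell markers (6.67 against 3.42 and 4.23). With all arrays the last 3 lists had 0 calls each with limma (0 adjusted over the list alone) and medians of -0.28, 0.16 and -0.28. Without that array 5 of 16 MHC class II genes were lower (median -0.56), 12 of 24 interferon-gamma genes (-1.10), 5 of 26 type I interferon genes (-0.79) and 3 of 11 natural killer cell markers (-1.63). Leaving out any other array gave 1 or 2 MHC class II genes lower.

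Over all 12577 genes tested, 1193 were higher and 657 lower in neuroblastoma at an adjusted p under 0.05 with limma. Leaving out EG7_model array 1, 2 or 3 gave 704, 990 and 985 genes. With the EG7 arrays of both experiments in the fit the count was 3000, of which 94.7% were higher against 64.5% in the main comparison.

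The same tumour and host genotype was measured in both bead-enriched experiments. The 5 WT arrays of the Myd88 experiment and the 3 EG7 arrays of the tumour model experiment differed in 11390 of 12629 genes, with 99 higher and 11291 lower in the Myd88 experiment, and a median log2 difference of -1.07 over all genes. After joint quantile normalization 5613 genes differed, 2029 higher (36.1%, from 0.9%) and 3584 lower. Of these 4718 had differed before, 1035 with the opposite sign. Levels are therefore not compared across these experiments.

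In CD11b-enriched cells of EG7 tumours from Myd88-/- hosts, Il23a, the p19 subunit of interleukin-23, fell from a mean log2 signal of 8.64 to 4.37, a difference of -4.27 ± 0.15 (n = 5 each, limma adjusted p = 5.13e-09). Csf3, which encodes granulocyte colony-stimulating factor, fell by 2.88 ± 0.34. Lower too were the B cell chemoattractant Cxcl13 (-2.53 ± 0.26) and Nfkbiz (-1.73 ± 0.12, adjusted p = 6.61e-06), a nuclear regulator of NF-kB targets. The other largest falls were Schip1 (-1.66 ± 0.17), Mrgpra2b (-1.64 ± 0.20), the fatty acid receptor Gpr84 (-1.56 ± 0.14), the dicarboxylate transporter Slc13a3 (-1.55 ± 0.21), the interleukin-1 family cytokine Il1f9 (-1.55 ± 0.17) and the co-stimulatory ligand Tnfsf9 (-1.49 ± 0.12). Itga9, an integrin chain, rose by 1.05 ± 0.13 (adjusted p = 0.00115), Mfge8, which bridges apoptotic cells to phagocytes, by 0.93 ± 0.20, Zranb3 by 0.91 ± 0.17, the hypoxia-inducible Ankrd37 by 0.86 ± 0.15 and Tmem158 by 0.85 ± 0.12. Bcar3 (0.71 ± 0.15), the ectonucleotidase Nt5e (0.68 ± 0.11), Cdk20 (0.63 ± 0.10), Prr15 (0.63 ± 0.13) and Sdcbp2 (0.57 ± 0.10) followed. Itga9 and Tmem158 neighbour Myd88, within 10 Mb of it in assembly GRCm38.p6.

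**Figure D2:**
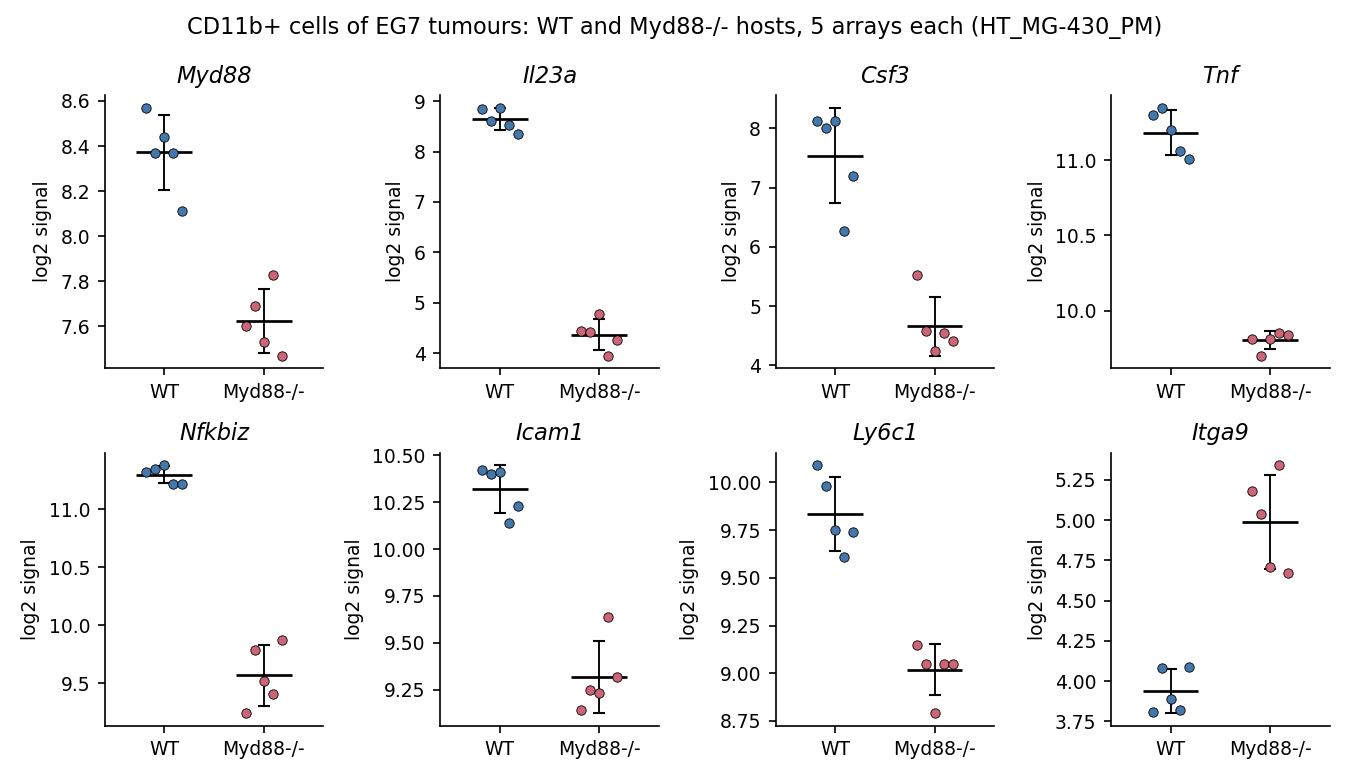
Log2 signal (y axis) of 8 genes in CD11b-enriched cells of EG7 tumours from WT and Myd88-/- hosts (x axis), 5 arrays each. Points are arrays, the horizontal line is the mean and the error bar is 1 SD. Itga9 lies higher in every Myd88-/- array than in any WT array.

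Of 30 NF-kB targets and feedback genes, 19 fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.62 and a camera adjusted p = 1.63e-41, or adjusted p = 0.0537 with an estimated correlation. Falls came in the adhesion molecule Icam1 (-1.0 ± 0.10), the signalling adaptor Traf1 (-0.97 ± 0.11) and the apoptosis inhibitor Birc3 (-0.86 ± 0.09). Inflammatory cytokines and chemokines fell for 13 of 30 (19 adjusted over the list alone, median -0.48, adjusted p = 5.34e-25), including Tnf at -1.38 ± 0.08. The call was lost, at adjusted p = 0.0537 with an estimated correlation. Monocyte markers fell for 10 of 18 (16 lower and 1 higher adjusted over the list alone, median -0.49, adjusted p = 8.6e-20), and this call held with adjusted p = 0.0335 with an estimated correlation. The surface marker of inflammatory monocytes Ly6c1 fell by 0.82 ± 0.10, with further falls in Treml4 (-0.99 ± 0.13), Ms4a4c (-1.01 ± 0.14) and Ms4a6c (-0.42 ± 0.07). Of 23 immediate-early and dissociation stress genes, 6 fell (7 adjusted over the list alone, median -0.15, adjusted p = 7.39e-05), among them the phosphatase gene Dusp2 at -1.19 ± 0.09, Nr4a1 at -0.56 ± 0.10 and Egr1 at -0.51 ± 0.10. For that list adjusted p = 0.611 with an estimated correlation.

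Type I interferon response genes had 1 fall among 27 (6 adjusted over the list alone, median -0.34, adjusted p = 6.26e-11), Usp18 at -0.89 ± 0.17. This list call did not hold, at adjusted p = 0.611 with an estimated correlation. The interferon-gamma response list had 0 calls among 23 (3 lower adjusted over the list alone, median -0.30, adjusted p = 1.55e-07), with Irf1 at -0.59 ± 0.15 (adjusted p = 0.0881) and Cxcl11 at -1.22 ± 0.32 (adjusted p = 0.0996). That list gave adjusted p = 0.611 with an estimated correlation. Of 32 TLR, IL-1R and TNFR pathway components, 3 fell (5 lower and 1 higher adjusted over the list alone, median -0.03, adjusted p = 0.026). The list gave adjusted p = 0.22 with an estimated correlation. The fallen components were Myd88 itself, the feedback kinase Irak3 at -0.95 ± 0.15 and Tnfrsf1b at -0.50 ± 0.09. Matrix remodelling and angiogenesis genes had 1 rise, the protease Adam8 at 0.37 ± 0.08, and 1 fall, the growth factor Ereg at -1.17 ± 0.18, among 27 (7 higher and 1 lower adjusted over the list alone, median 0.18, adjusted p = 0.0114, adjusted p = 0.65 with an estimated correlation). The 29 alternative activation genes had 0 calls (0 adjusted over the list alone, median 0.00, adjusted p = 0.652), with Cd209a at -0.71 ± 0.18 and Msr1 at 0.30 ± 0.09. Of 20 neutrophil markers 2 fell, Il1f9 and Asprv1 (-0.86 ± 0.19), with 5 adjusted over the list alone, a median of -0.20 and an adjusted p = 3.25e-05. That call gave adjusted p = 0.611 with an estimated correlation, and the most abundant neutrophil genes S100a9 and S100a8 differed by -0.19 and -0.05. Cell cycle genes had 0 calls among 30 (0 adjusted over the list alone, median 0.04, adjusted p = 0.683), with Mki67 at -0.40 ± 0.11.

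Over 11915 genes, 31 rose and 141 fell with limma. With 1 array left out at a time, the lowest number of rises was 7 and the highest 39, and of falls 77 and 242. Leaving out EG7_WT array 2 changed the count of 172 to 86 genes, EG7_WT array 3 gave 88, EG7_WT array 4 gave 275, EG7_Myd88KO array 3 gave 108 and EG7_Myd88KO array 5 gave 96. The 3' minus 5' signal of actin probes, a sign of RNA degradation, averaged 0.69 in Myd88-/- and 0.6 in WT arrays (exact permutation p = 0.0397, two-sided, n = 5 each), and that of Gapdh probes 0.37 and 0.32 (exact permutation p = 0.413).

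In the sorted cells of WT hosts, population A was compared with population C. Retnlg, a resistin-like factor of granulocytes and monocytes, was higher in A by 5.14 ± 0.35 (n = 2 each, limma adjusted p = 8.01e-06), the lipoxygenase Alox15 by 4.18 ± 0.44, Ly6a2 by 4.15 ± 0.31, coagulation factor F5 by 3.45 ± 0.55 and the peptidoglycan-binding Pglyrp1 by 3.03 ± 0.58. Ace (2.94 ± 0.32), Cd24a (2.94 ± 0.41), Ifitm6 (2.93 ± 0.50), Gapt (2.80 ± 0.42) and the granule gene Ngp (2.74 ± 0.58) followed. Lower in A were the chemokine Ccl8 (-3.69 ± 0.41), the complement genes C1qc (-3.63 ± 0.33) and C1qa (-3.34 ± 0.25), Ms4a7 (-3.63 ± 0.29), the proton pump subunit Atp6v0d2 (-3.33 ± 0.50) and the aminopeptidase Anpep (-3.25 ± 0.45). The folate receptor Folr2 (-3.21 ± 0.22), platelet factor Pf4 (-3.15 ± 0.38), H2-M2 (-3.08 ± 0.42) and the mannose receptor Mrc1 (-3.08 ± 0.38) were also lower.

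Mature macrophage markers were lower in A for 19 of 25 and higher for 2 (21 and 2 adjusted over the list alone, median -1.26, adjusted p = 1.77e-13, adjusted p = 0.203 with an estimated correlation). Monocyte markers were higher for 5 of 20 (5 adjusted over the list alone, median 0.64, adjusted p = 0.000306), with Ly6c2 at 2.66 ± 0.36 and Plac8 at 2.46 ± 0.35. This became adjusted p = 0.615 with an estimated correlation. MHC class II presentation genes, used in the gate, were lower for 7 of 15 (9 adjusted over the list alone, median -0.60, adjusted p = 4.4e-05), including H2-Eb1 at -2.13 ± 0.41 and H2-Aa at -2.10 ± 0.43. The call was lost, at adjusted p = 0.422 with an estimated correlation. Lipid and cholesterol handling genes were lower for 12 of 19 (13 adjusted over the list alone, median -0.75, adjusted p = 6.81e-07), among them the fatty acid binding protein Fabp5 at -3.02 ± 0.37 and the cholesterol exporter Abca1 at -2.45 ± 0.27. This list call did not hold, at adjusted p = 0.231 with an estimated correlation. Matrix remodelling and angiogenesis genes were lower for 12 of 28 (13 lower and 1 higher adjusted over the list alone, median -0.67, adjusted p = 0.000123), with Igf1 at -2.56 ± 0.26 and Timp2 at -2.13 ± 0.30. The list gave adjusted p = 0.418 with an estimated correlation. Hypoxia and glycolysis genes were lower for 7 of 25 (12 adjusted over the list alone, median -0.62, adjusted p = 1.71e-05), with P4ha1 at -1.05 ± 0.18 and at adjusted p = 0.597 with an estimated correlation. Neutrophil markers were higher for 8 of 22 (8 adjusted over the list alone, median 0.42, adjusted p = 1.11e-05), with Lcn2 at 1.90 ± 0.21, and this call held with adjusted p = 0.049 with an estimated correlation.

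Markers of cells outside the macrophage lineage also separated the populations. Eosinophil and mast cell markers were higher in A for 2 of 11 (2 adjusted over the list alone, median 0.81, adjusted p = 0.000299), Ccr3 at 2.57 ± 0.42 and Siglecf at 2.22 ± 0.56. This became adjusted p = 0.51 with an estimated correlation. Fibroblast markers were higher for 8 of 15 (8 adjusted over the list alone, median 0.46, adjusted p = 4.04e-06), including Dcn at 2.19 ± 0.31 and Col1a1 at 1.53 ± 0.27. The call was lost, at adjusted p = 0.221 with an estimated correlation. Natural killer cell markers were higher for 4 of 11 and lower for 1 (5 and 1 adjusted over the list alone, median 0.36, adjusted p = 0.00974), with Nkg7 at 1.24 ± 0.25. This list call did not hold, at adjusted p = 0.577 with an estimated correlation. Of 10 B lymphocyte markers 2 were lower (2 lower and 4 higher adjusted over the list alone, median 0.27, adjusted p = 0.555), Cd22 at -1.67 ± 0.25 and Blnk at -1.49 ± 0.23. In all, 583 genes were higher and 1640 lower in A among 16524 tested. Leaving out C_WT array 1 changed the count of 2223 to 406 genes and A_WT array 1 gave 3429. Without A_WT array 2, 946 were higher and 1283 lower, so that the share higher moved from 26.2% to 42.4%.

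Genotype effects within population A were large for many genes but rested on 2 arrays per group. In TNFR1-/- hosts, Saa3, an acute-phase apolipoprotein, fell by 2.50 ± 0.43 (n = 2 each, limma adjusted p = 0.0303). Falls followed in Gpr84 (-2.49 ± 0.22, adjusted p = 0.000268), the membrane protease Mmp14 (-2.22 ± 0.33), Igfbp7 (-1.97 ± 0.29) and the formyl peptide receptor Fpr2 (-1.94 ± 0.37). The rises were led by the type 2 cytokine Il13 (2.85 ± 0.54), the eotaxin receptor Ccr3 (2.73 ± 0.42), Serpinb2 (2.64 ± 0.50), Siglecg (2.53 ± 0.52) and Bank1 (2.35 ± 0.44). NF-kB targets and feedback genes fell for 2 of 30, Sod2 (-1.94 ± 0.33) and Saa3 (13 lower and 1 higher adjusted over the list alone, median -0.53, adjusted p = 7.31e-05, adjusted p = 0.633 with an estimated correlation). Fibroblast markers fell for 5 of 15 (6 adjusted over the list alone, median -0.31, adjusted p = 1.03e-06), with Postn at -1.13 ± 0.14. The list gave adjusted p = 0.203 with an estimated correlation. T lymphocyte and EG7 line markers fell for 2 of 18 (7 adjusted over the list alone, median -0.37, adjusted p = 3.88e-05), Cd3e at -1.16 ± 0.23 and Cd3g at -1.11 ± 0.23. This became adjusted p = 0.408 with an estimated correlation. Eosinophil and mast cell markers had 1 rise among 11, Ccr3 (3 adjusted over the list alone, median 1.28, adjusted p = 0.00344, adjusted p = 0.6 with an estimated correlation). Xist differed by -4.45 ± 1.65 (adjusted p = 0.176), with Xist at 10.1 and 9.45 in A_WT against 5.36 and 5.29 in A_TNFR1KO, so that Xist splits exactly with genotype here. Some sorted arrays carried both Xist and the Y-linked Eif2s3y, at 10.14 and 6.29 in C_WT array 1, 9.83 and 5.92 in C_TNFR1KO array 2 and 8.43 and 6.14 in A_Myd88cKO array 2, so Xist alone does not give the sex of a sample. With limma 52 genes rose and 56 fell. Without A_WT array 1 the count of 108 became 5, without A_WT array 2 it was 1750 (619 higher and 1131 lower), without A_TNFR1KO array 1 it was 403 (287 and 116) and without A_TNFR1KO array 2 it was 2.

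Several lists were also lower as a whole for TNFR1-/- in A, and none of these calls held. Neutrophil markers had 1 rise and 4 falls among 22 (3 and 9 adjusted over the list alone, median -0.22, camera adjusted p = 0.0304, adjusted p = 0.221 with an estimated correlation), with Elane at -0.98 ± 0.15 and Lcn2 at -1.29 ± 0.21. Monocyte markers had 0 calls among 20 (1 higher and 6 lower adjusted over the list alone, median -0.54, adjusted p = 0.00246, adjusted p = 0.648 with an estimated correlation). Of 25 mature macrophage markers Cx3cr1 fell, at -1.12 ± 0.18 (2 higher and 9 lower adjusted over the list alone, median -0.42, adjusted p = 0.000807, adjusted p = 0.612 with an estimated correlation). Of 14 endothelial markers Cdh5 fell, at -1.18 ± 0.18 (4 adjusted over the list alone, median -0.35, adjusted p = 0.000786, adjusted p = 0.225 with an estimated correlation), and of 11 natural killer cell markers Ccl5, at -1.92 ± 0.34 (4 adjusted over the list alone, median -0.22, adjusted p = 0.00471, adjusted p = 0.512 with an estimated correlation). Cell cycle genes had 0 calls among 29 (1 lower adjusted over the list alone, median -0.28, adjusted p = 0.000835, adjusted p = 0.6 with an estimated correlation).

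In population A of Myd88 cKO hosts, the potassium channel gene Kcnma1 rose by 4.20 ± 0.96 (n = 2 each, limma adjusted p = 0.0355), Atp6v0d2 by 3.86 ± 0.50, Ccl8 by 3.75 ± 0.41 (adjusted p = 0.000822), Retnla, a marker of alternative activation, by 3.18 ± 0.58 and H2-M2 by 3.13 ± 0.42. Besides Myd88 at -2.07 ± 0.27 (adjusted p = 0.00317), the largest falls were Treml4 (-1.66 ± 0.38), the angiotensin-converting enzyme Ace (-1.64 ± 0.32), Cldn34b3 (-1.47 ± 0.29) and the heat shock gene Hspa1b (-1.37 ± 0.35). Mature macrophage markers rose for 10 of 25 and fell for 1 (11 and 2 adjusted over the list alone, median 0.54, adjusted p = 1.23e-07, adjusted p = 0.377 with an estimated correlation), with Folr2 at 2.52 ± 0.22, Ms4a7 at 2.79 ± 0.29 and C1qa at 2.30 ± 0.25. Alternative activation genes rose for 9 of 29 (12 adjusted over the list alone, median 0.74, adjusted p = 1.06e-07), including Mrc1 at 2.43 ± 0.38, Pdcd1lg2 at 2.10 ± 0.32 and the arginase Arg1 at 2.09 ± 0.45. The call was lost, at adjusted p = 0.366 with an estimated correlation. Matrix remodelling and angiogenesis genes rose for 6 of 28 (15 adjusted over the list alone, median 0.69, adjusted p = 9.94e-10), with Igf1 at 2.43 ± 0.26. This list call did not hold, at adjusted p = 0.197 with an estimated correlation. NF-kB targets and feedback genes had 1 fall among 30, Nfkbiz at -1.32 ± 0.29 (1 adjusted over the list alone, median -0.44, adjusted p = 1.92e-05, adjusted p = 0.615 with an estimated correlation). Eosinophil and mast cell markers had 1 rise among 11, Ccr3 at 2.18 ± 0.42 (5 adjusted over the list alone, median 0.95, adjusted p = 0.0132, adjusted p = 0.648 with an estimated correlation).

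Monocyte markers had 1 rise, Chil3 at 1.95 ± 0.50, and 1 fall, Treml4, among 20 in Myd88 cKO of population A (2 and 7 adjusted over the list alone, median -0.82, camera adjusted p = 0.000123, adjusted p = 0.6 with an estimated correlation). Of 14 endothelial markers Cdh5 rose by 1.39 ± 0.18 (4 adjusted over the list alone, median 0.43, adjusted p = 0.00657). That call gave adjusted p = 0.366 with an estimated correlation and a fry adjusted p = 0.0256. Natural killer cell markers had 0 calls among 11 (0 adjusted over the list alone, median -0.38, adjusted p = 0.00442, adjusted p = 0.51 with an estimated correlation), with Klrb1c at -0.59 ± 0.20 and Nkg7 at -0.70 ± 0.25. With limma 408 genes rose and 117 fell in Myd88 cKO of population A, and after quantile normalization 335 rose and 170 fell, so that the share of rises moved from 77.7% to 66.3%. Leaving out A_WT array 1 gave 1516 genes (1246 higher and 270 lower), A_WT array 2 gave 1129 (550 and 579, 48.7% higher), A_Myd88cKO array 1 gave 165 and A_Myd88cKO array 2 gave 8. Array weights by group left 9 genes called.

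In double KO hosts, population A showed rises of Retnla (2.66 ± 0.58), Serpinb2 (2.51 ± 0.50), Tmem64 (2.51 ± 0.58), Il13 (2.45 ± 0.54), Ccl8 (2.36 ± 0.41), Ccr3 (2.26 ± 0.42), Rgs18 (2.20 ± 0.42), Bank1 (2.19 ± 0.44), Siglecg (2.13 ± 0.52) and the glucose transporter Slc2a3 (2.12 ± 0.40). The cytokine Tnf fell by 1.89 ± 0.38 (n = 2 each, limma adjusted p = 0.0197). Lower with it were Myd88 (-1.78 ± 0.27), the inflammasome sensor Nlrp3 (-1.49 ± 0.41), Nfkbiz (-1.33 ± 0.29) and Gpr84 (-1.22 ± 0.22). Cldn34b3 (-1.42 ± 0.29), Treml4 (-1.36 ± 0.38), Ifitm2 (-1.34 ± 0.29), Adh6b (-1.23 ± 0.26) and Olfr763 (-1.19 ± 0.27) were the remaining large falls. NF-kB targets and feedback genes fell for 5 of 30 (10 adjusted over the list alone, median -0.52, adjusted p = 2.67e-08, adjusted p = 0.498 with an estimated correlation). Cell cycle genes rose for 14 of 29 (21 adjusted over the list alone, median 0.67, adjusted p = 6.55e-11), among them the ribonucleotide reductase subunits Rrm1 at 1.23 ± 0.19 and Rrm2 at 1.17 ± 0.20. The list gave adjusted p = 0.221 with an estimated correlation. Beside them, T lymphocyte and EG7 line markers rose for 5 of 18 (5 adjusted over the list alone, median 0.26, adjusted p = 0.0105), including Cd3g at 1.75 ± 0.23, Cd3e at 1.35 ± 0.23, Lat at 1.19 ± 0.25 and Thy1 at 1.02 ± 0.26. This became adjusted p = 0.633 with an estimated correlation. Eosinophil and mast cell markers rose for 2 of 11, Ccr3 and Il5ra at 1.54 ± 0.35 (7 adjusted over the list alone, median 1.29, adjusted p = 0.00759, adjusted p = 0.633 with an estimated correlation). Counted over all genes, 715 rose and 235 fell with limma, and leaving out A_WT array 1 gave 2345 genes whereas leaving out A_doubleKO array 1 gave 2. Without A_WT array 2, 629 were higher and 661 lower, so that the share higher moved from 75.3% to 48.8%. With array weights by group, or only the 4 arrays compared, limma called 0 genes, against 950 in the main fit (4095 at an unadjusted p under 0.05).

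**Figure D3:**
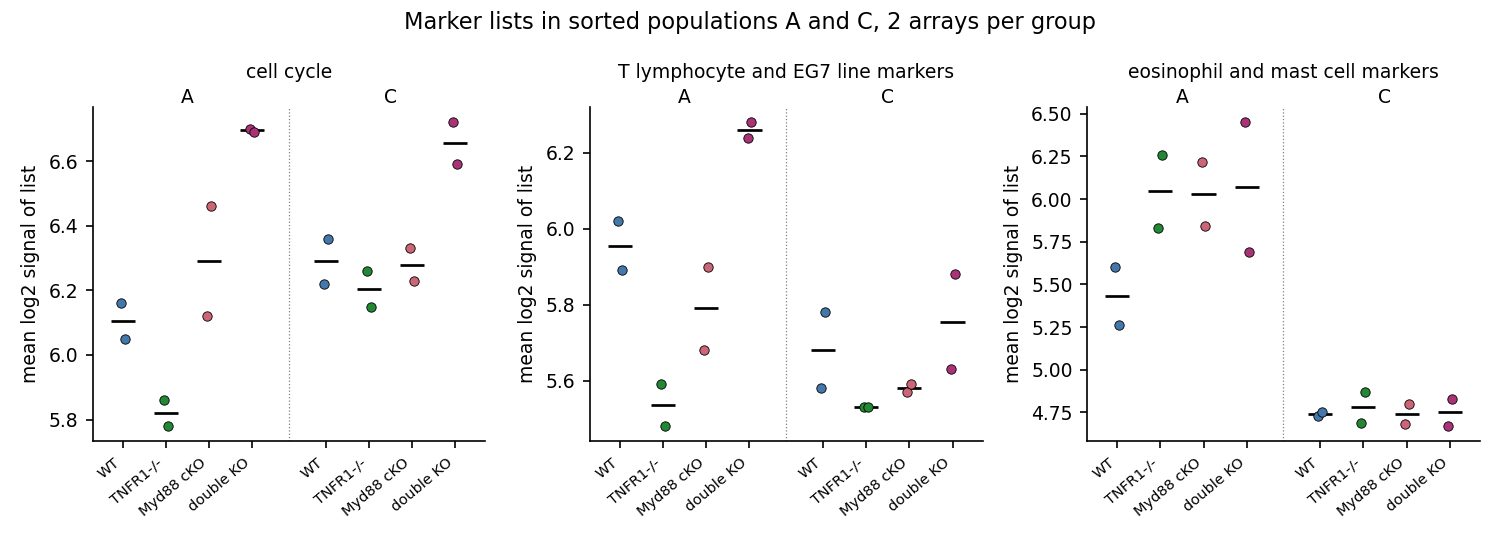
Mean log2 signal (y axis) of 3 gene lists in sorted populations A and C by host genotype (x axis), 2 arrays per group. Points are arrays and the line is their mean. In population A the cell cycle list lies at 6.7 and 6.69 in double KO against 6.16 and 6.05 in WT, and the T lymphocyte and EG7 line list at 6.24 and 6.28 against 6.02 and 5.89.

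In population C of TNFR1-/- hosts, the chemokine Ccl17 rose by 2.63 ± 0.31 (n = 2 each, limma adjusted p = 0.00292), and the lectins Mgl2 and Cd209d rose by 2.35 ± 0.23 and 2.03 ± 0.22. The endothelin receptor Ednrb (1.21 ± 0.20) and the transcription factor Stat4 (1.18 ± 0.18) also rose. H2-M2 fell by 3.25 ± 0.42, ahead of Saa3 (-2.92 ± 0.43), Gpr84 (-2.06 ± 0.22), the ubiquitin ligase Rnf128 (-1.82 ± 0.30) and Gdpd1 (-1.62 ± 0.24). Alternative activation genes rose for 3 of 29 (10 adjusted over the list alone, median 0.55, adjusted p = 1.16e-17). The call was lost, at adjusted p = 0.15 with an estimated correlation. Dendritic cell markers, of which 3 are also in that list, had 1 rise among 22, Ccl17 (7 adjusted over the list alone, median 0.41, adjusted p = 5.25e-13), and this call held with adjusted p = 0.0224 with an estimated correlation. Immediate-early and dissociation stress genes had 0 calls among 25 (0 adjusted over the list alone), but 24 lay above 0, with a median of 0.34 and an adjusted p = 1.44e-09. That list gave adjusted p = 0.288 with an estimated correlation, and its members of smallest p were Dusp2 at 0.63 ± 0.24 and Hsph1 at 0.78 ± 0.31. Inflammatory cytokines and chemokines had 0 calls among 30 (5 higher adjusted over the list alone, median 0.19, adjusted p = 2.37e-05, adjusted p = 0.0726 with an estimated correlation), with Il6 at 1.24 ± 0.25 and Il10 at 0.85 ± 0.23. Limma called 5 rises and 7 falls. Without C_WT array 1 the count of 12 became 5, without C_WT array 2 it was 2 and without C_TNFR1KO array 2 it was 4.

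In Myd88 cKO hosts, population C had 2 calls. Chil3, a chitinase-like protein of alternative activation and of monocytes, rose by 3.54 ± 0.50 (n = 2 each, limma adjusted p = 0.0464), and Myd88 fell by 1.99 ± 0.27 (adjusted p = 0.0464). Leaving out C_WT array 1, C_WT array 2, C_Myd88cKO array 1 or C_Myd88cKO array 2 gave 0 calls each time, and 636 genes had an unadjusted p under 0.05 with all arrays. Of 29 alternative activation genes, Chil3 was the 1 called (7 adjusted over the list alone, median 0.56, adjusted p = 3.15e-11). This list call did not hold, at adjusted p = 0.221 with an estimated correlation. Matrix remodelling and angiogenesis genes had 0 calls among 28 (6 adjusted over the list alone, median 0.25, adjusted p = 3.92e-08), with Mmp2 at 1.16 ± 0.27 and Timp1 at 1.27 ± 0.31. The list gave adjusted p = 0.221 with an estimated correlation.

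In population C of double KO hosts, Rnase2a, a ribonuclease, rose by 6.07 ± 0.83 (n = 2 each, limma adjusted p = 0.00491), Ccl17 by 4.10 ± 0.31 (adjusted p = 2.31e-05), Retnla by 4.05 ± 0.58, Mgl2 by 3.66 ± 0.23 (adjusted p = 3.09e-06), Ccl24 by 3.36 ± 0.51 and Ccl22 by 2.45 ± 0.31. Plet1 (2.59 ± 0.31), Bex6 (2.17 ± 0.38), Cd209d (2.06 ± 0.22) and the lymph node homing receptor Ccr7 (1.90 ± 0.28) also rose. Saa3 fell by 3.67 ± 0.43, ahead of the itaconate-making enzyme Acod1 (-3.19 ± 0.36), Fpr2 (-3.09 ± 0.37), H2-M2 (-2.80 ± 0.42), the lectin Clec4e (-2.55 ± 0.40) and haptoglobin Hp (-2.52 ± 0.42). Gpr84 (-2.50 ± 0.22, adjusted p = 8.27e-05), the Notch ligand Jag1 (-2.16 ± 0.35), the superoxide dismutase Sod2 (-1.78 ± 0.33) and the inducible nitric oxide synthase Nos2 (-1.76 ± 0.34) completed the largest falls. Clec4e neighbours Tnfrsf1a, within 10 Mb of it in assembly GRCm38.p6. Alternative activation genes rose for 8 of 29 (16 adjusted over the list alone, median 0.92, adjusted p = 3.31e-26). This became adjusted p = 0.0975 with an estimated correlation. Dendritic cell markers rose for 6 of 22 (10 adjusted over the list alone, median 0.45, adjusted p = 2.4e-15), among them the transcription factor Irf4 at 1.56 ± 0.21, and this call held with adjusted p = 0.0224 with an estimated correlation. NF-kB targets and feedback genes fell for 4 of 30 (7 adjusted over the list alone, median -0.41, adjusted p = 4.09e-14). The call was lost, at adjusted p = 0.301 with an estimated correlation. Inflammatory cytokines and chemokines had 1 fall among 30, Il1a at -1.63 ± 0.25 (6 lower and 2 higher adjusted over the list alone, median -0.20, adjusted p = 0.0155, adjusted p = 0.221 with an estimated correlation).

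Cell cycle genes had 0 calls among 29 for double KO in C (6 higher adjusted over the list alone, median 0.36, camera adjusted p = 6.14e-13, adjusted p = 0.203 with an estimated correlation), with Nusap1 at 0.70 ± 0.15 and Rrm1 at 0.79 ± 0.19. Limma called 29 rises and 22 falls, and after quantile normalization 23 rises and 30 falls, so that the share of rises moved from 56.9% to 43.4%. Without C_WT array 1 the count of 51 became 16, without C_WT array 2 it was 15 and without C_doubleKO array 2 it was 7. With only the 4 arrays compared in the fit it was 135.

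**Figure D4:**
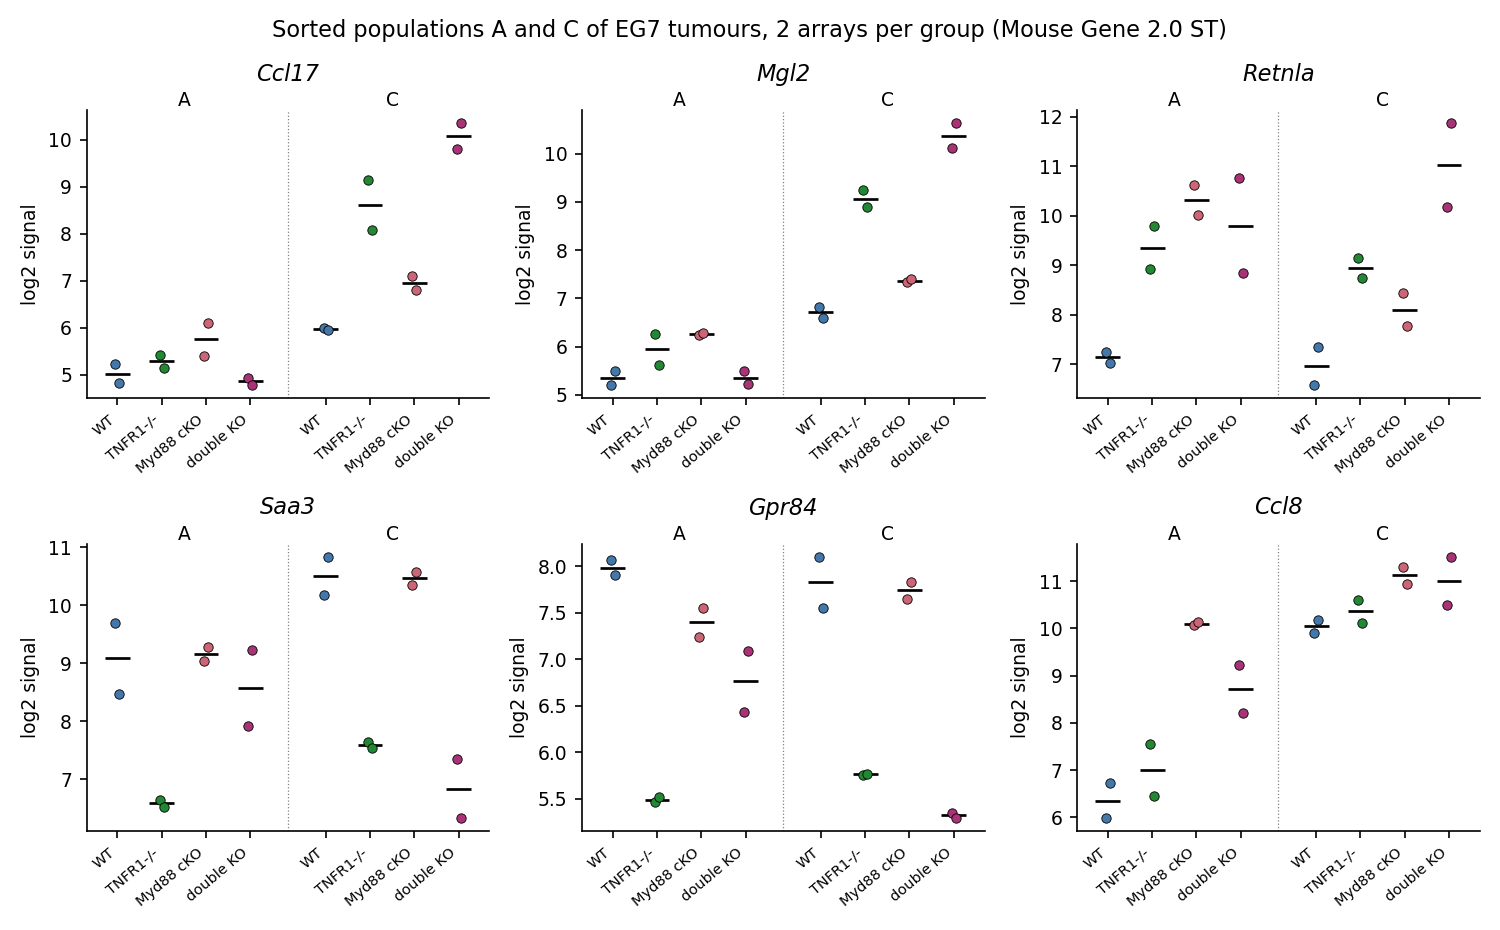
Log2 signal (y axis) of 6 genes in sorted populations A and C by host genotype (x axis), 2 arrays per group. Points are arrays and the line is their mean. In population C, Ccl17 is higher than WT by 2.63 in TNFR1-/- and by 4.10 in double KO.

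The double KO was set against each single genotype, averaged over A and C, to ask what the second change added. Relative to TNFR1-/-, Kcnma1 was higher by 3.42 ± 0.68 (n = 2 each in A and in C, limma adjusted p = 0.0274). Atp6v0d2 was higher by 1.85 ± 0.36, Cd3g by 1.82 ± 0.16, the histone gene H2ac15 by 1.68 ± 0.15 and Cd3e by 1.54 ± 0.16. Lower were Acod1 (-1.55 ± 0.26), Myd88 (-1.52 ± 0.19), Nfkbiz (-1.27 ± 0.21) and the cytokines Il10 (-1.07 ± 0.17) and Il6 (-1.04 ± 0.18). Cell cycle genes were higher for 17 of 29 (24 adjusted over the list alone, median 0.70, adjusted p = 8.72e-36), including Rrm2 at 1.25 ± 0.14 and Cdk1 at 1.27 ± 0.17, and this call held with adjusted p = 0.049 with an estimated correlation. Beside them 5 of 18 T lymphocyte and EG7 line markers were higher (10 adjusted over the list alone, median 0.35, adjusted p = 4.73e-12, adjusted p = 0.164 with an estimated correlation). Inflammatory cytokines and chemokines were lower for 4 of 30 (8 lower and 1 higher adjusted over the list alone, median -0.15, adjusted p = 2.86e-07), and this call held with adjusted p = 0.049 with an estimated correlation. In all 140 genes were higher and 10 lower. The count of 150 became 60 without C_TNFR1KO array 1, 34 without C_TNFR1KO array 2, 69 without C_doubleKO array 1, 44 without C_doubleKO array 2, 61 without A_TNFR1KO array 2, 73 without A_doubleKO array 1 and 83 without A_doubleKO array 2.

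Relative to Myd88 cKO, the double KO had lower H2-M2 (-3.00 ± 0.30, n = 2 each in A and in C, limma adjusted p = 0.000529), Saa3 (-2.11 ± 0.31), Rnf128 (-1.76 ± 0.21), Acod1 (-1.72 ± 0.26) and the cathepsin Ctsk (-1.66 ± 0.29). Higher were Bex6 (1.69 ± 0.27), the cyclin Ccnd2 (1.51 ± 0.21), the amino acid transporter Slc7a5 (1.36 ± 0.22), Cd3g (1.26 ± 0.16) and H2ac15 (1.25 ± 0.15). Mature macrophage markers were lower for 4 of 25 and higher for 1 (14 and 1 adjusted over the list alone, median -0.52, adjusted p = 9.16e-12, adjusted p = 0.221 with an estimated correlation), with Ms4a7 at -1.61 ± 0.21. Matrix remodelling and angiogenesis genes were lower for 6 of 28 (11 adjusted over the list alone, median -0.42, adjusted p = 2.27e-12), with Mmp2 at -1.57 ± 0.19. This list call did not hold, at adjusted p = 0.15 with an estimated correlation. Cell cycle genes were higher for 7 of 29 (18 higher and 1 lower adjusted over the list alone, median 0.44, adjusted p = 2.05e-17), with adjusted p = 0.15 with an estimated correlation, and T lymphocyte and EG7 line markers for 3 of 18 (7 higher and 1 lower adjusted over the list alone, median 0.24, adjusted p = 3.7e-08, adjusted p = 0.221 with an estimated correlation). In all 58 genes were higher and 92 lower. The count of 150 became 52 without C_Myd88cKO array 1, 76 without C_Myd88cKO array 2, 96 without C_doubleKO array 1 and 88 without C_doubleKO array 2. Without A_Myd88cKO array 2, 61 were higher and 47 lower, and without A_Myd88cKO array 1, 31 and 111.

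Whether the double effect equalled the sum of the single effects was tested directly. In population A, 12 genes lay above the sum and 0 below it with limma. They were led by Cd3g (2.81 ± 0.33, adjusted p = 0.00492), Cd3e (2.53 ± 0.33), Thy1 (2.34 ± 0.36), the asparagine synthetase Asns (2.29 ± 0.36) and H2ac15 (2.26 ± 0.31). T lymphocyte and EG7 line markers exceeded the sum for 3 of 18 (8 adjusted over the list alone, median 0.68, adjusted p = 5.25e-13, adjusted p = 0.15 with an estimated correlation). The count of 12 became 3 without A_WT array 1 (2 above the sum and 1 below), 545 without A_WT array 2 (352 and 193), 6 without A_TNFR1KO array 1, 3 without A_Myd88cKO array 1, 83 without A_doubleKO array 1 (37 and 46) and 3 without A_doubleKO array 2. In population C limma called 0 genes, with 433 at an unadjusted p under 0.05. As a list, the inflammatory cytokines and chemokines of population C fell short of the sum, with a median of -0.34 over 30 genes and 0 single calls (3 lower adjusted over the list alone, adjusted p = 1.89e-10), and this call held with adjusted p = 0.0224 with an estimated correlation. Its members of smallest p were Cxcl3 at -1.88 ± 0.31 (adjusted p = 0.445) and Il1a at -1.62 ± 0.35 (adjusted p = 0.975).

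Differences of a genotype effect between the populations were tested as interactions. For double KO, 6 genes differed with limma. Ccl17 (-4.26 ± 0.44, adjusted p = 0.00112), Mgl2 (-3.66 ± 0.32, adjusted p = 0.000281), Plet1 (-2.89 ± 0.44) and Cd209d (-2.21 ± 0.31) had lower effects in A than in C, and Gdpd1 (2.20 ± 0.34) and Exoc6b (1.24 ± 0.19) had positive differences. Of 22 dendritic cell markers 1 was lower, Ccl17 (6 adjusted over the list alone, median -0.49, adjusted p = 2.63e-08), and this call held with adjusted p = 0.049 with an estimated correlation. The count of 6 became 2 without C_WT array 1, 3 without C_doubleKO array 2, 2 without A_WT array 1, 97 without A_WT array 2 and 72 without A_doubleKO array 2. For TNFR1-/- limma called 0 genes, with 1533 at an unadjusted p under 0.05, and for Myd88 cKO 0 genes, with 1505. Without A_WT array 2 these counts were 295 and 36, and without C_TNFR1KO array 2 the TNFR1-/- count was 2.

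The genes called in Myd88-/- hosts were followed in the sorted arrays, another chip and another deletion. In Myd88 cKO of population C, 116 of 130 genes that fell in Myd88-/- hosts had a difference of the same direction, with a median of -0.23 (camera adjusted p = 1.26e-10, adjusted p = 0.278 with an estimated correlation), and 24 of 29 that rose had a median of 0.34 (adjusted p = 1.15e-11, adjusted p = 0.116 with an estimated correlation). In double KO of population C, 99 of 130 had the same direction (median -0.21, adjusted p = 3.06e-12, adjusted p = 0.278 with an estimated correlation). In population A the fallen genes had medians of -0.25 in Myd88 cKO (93 of 130, adjusted p = 4.04e-05, adjusted p = 0.532 with an estimated correlation) and -0.29 in double KO (92 of 130, adjusted p = 6.33e-05, adjusted p = 0.532 with an estimated correlation). For TNFR1-/- in A 82 of 130 had the same direction (adjusted p = 0.0325, adjusted p = 0.782 with an estimated correlation), and in C 51 of 130 (adjusted p = 0.0965). The risen genes had medians of 0.26 in Myd88 cKO of A (20 of 29, adjusted p = 6.33e-05, adjusted p = 0.278 with an estimated correlation), 0.03 in double KO of A (15 of 29, adjusted p = 0.394) and 0.06 in double KO of C (16 of 29, adjusted p = 0.925). For TNFR1-/- they had the same direction for 9 of 29 in A (median -0.10, adjusted p = 0.925) and for 9 of 29 in C (median -0.08, adjusted p = 0.394). Of the 12 tests, 7 were called at the preset correlation and 0 with an estimated one, and fry called 0.

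The genotype effects of one population share their WT arrays, which alone correlates them. In A the effects correlated across 16524 genes at 0.65 for TNFR1-/- with Myd88 cKO, 0.71 for TNFR1-/- with double KO and 0.82 for Myd88 cKO with double KO, against 0.5 in simulations of unchanged groups. Their covariances were 0.099, 0.11 and 0.13 against a simulated 0.034. Myd88 cKO and double KO shared 245 rises and 68 falls, where independent lists of that size would share 17.7 and 1.7. TNFR1-/- and double KO shared 48 rises and 14 falls (2.3 and 0.8), and TNFR1-/- and Myd88 cKO 39 and 13 (1.3 and 0.4). In C the correlations were 0.31, 0.67 and 0.4 in the same order, with covariances of 0.016, 0.041 and 0.024 against a simulated 0.017, and only TNFR1-/- and double KO shared calls, 5 rises and 5 falls. Genes are not independent replicates. After the data were seen, each effect of a pair also had 1 own WT array as control, both ways round. In A the correlations were then 0.1 and 0.32, 0.13 and 0.39, and 0.32 and 0.36 in the same order, with covariances of 0.022 and 0.061, 0.03 and 0.074, and 0.07 and 0.076. In C they were -0.05 and -0.1, 0.26 and 0.21, and 0.02 and 0.03. The shared calls were not recounted with separate controls.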

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

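The tests of passenger DNA in each of the 4 comparisons alone, of neutrophils as the whole source of the falls and of eosinophils as the source of the cell cycle rises, of A_WT array 2 for double KO and of either A_WT array for TNFR1-/-, and the fits with the Xist or Eif2s3y level, were chosen after the results were seen.

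Single arrays stood far from the rest of their group in 7 of 144 groups of 5 arrays, and chance alone gives about 1 in 20 groups. The gap to the nearest array, as a share of the range of the group, was 0.74 for Csf3 in EG7_Myd88KO array 1 (log2 signal 5.52, nearest 4.58), 0.733 for Tnf in array 2 (9.7, nearest 9.81) and 0.722 for Ly6c1 in array 3 (8.79, nearest 9.05). For list means it was 0.833 for type I interferon response in EG7_Myd88KO array 3 (6.2, nearest 6.5), 0.882 for monocyte markers in array 2 (8.48, nearest 8.33), 0.765 for fibroblast markers in EG7_WT array 5 (6.93, nearest 7.06) and 0.744 for endothelial markers in EG7_WT array 1 (5.14, nearest 5.43).

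The effect of the double KO differed between populations A and C in a test of the difference itself. It was lower in A for Ccl17 (-4.26), Mgl2 (-3.66), Plet1 (-2.89) and Cd209d (-2.21), and higher in A for Gdpd1 (2.20) and Exoc6b (1.24). Gene lists were tested for the same differences, and 35 of 75 were called at the preset correlation, of which 1 held with an estimated correlation, the dendritic cell markers for the double KO (adjusted p = 0.049). For TNFR1-/- the called median differences were -0.42 for NF-kB targets, -0.41 for alternative activation, -0.31 for type I interferon response, -0.59 for MHC class II presentation, -0.66 for monocyte, -0.28 for mature macrophage, -0.43 for dendritic cell, -0.29 for neutrophil, -0.23 for T lymphocyte and EG7 line, -0.60 for natural killer cell, 1.23 for eosinophil and mast cell, -0.42 for fibroblast and -0.33 for endothelial markers, -0.20 for cell cycle and -0.39 for immediate-early genes (adjusted p from 0.0986 to 0.689 with an estimated correlation). For Myd88 cKO they were -0.37 for NF-kB targets, 0.12 for MHC class II presentation, -0.53 for monocyte, 0.58 for mature macrophage, -0.39 for natural killer cell, 0.75 for eosinophil and mast cell and 0.35 for endothelial markers, 0.24 for cell cycle, 0.28 for hypoxia, 0.62 for lipid handling and 0.47 for matrix genes (0.346 to 0.728). For the double KO they were -0.66 for alternative activation, -0.49 for dendritic cell, 0.25 for T lymphocyte and EG7 line, -0.28 for B lymphocyte, 1.32 for eosinophil and mast cell and 0.27 for fibroblast markers, 0.23 for cell cycle, 0.62 for hypoxia and 0.52 for matrix genes (0.286 to 0.689 for the others than dendritic cell markers).

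The calls of Myd88-/- against WT were weighed against DNA carried along with the deletion. Of 107 tested genes within 10 Mb of Myd88 in assembly GRCm38.p6, 8 were called (7.48%), against 163 of 11785 elsewhere (1.38%), a ratio of 5.41, so passenger DNA is a candidate explanation for calls such as Itga9, Lars2 and Vill. Those genes differed in Myd88-/- hosts by 1.05, -1.36 and -0.68, and in sorted Myd88 cKO cells by 0.25, 0.00 and -0.01 in A and by -0.09, -0.06 and -0.12 in C. The chemokine receptor genes Ccr2 and Ccrl2, also in the region, differed by -1.07 and -0.65 in Myd88-/- hosts, by -0.94 and -0.24 in Myd88 cKO of A, -0.20 and -0.15 in C, -0.64 and -0.25 in double KO of A and 0.59 and -0.91 in C. None of these sorted values of Ccr2 and Ccrl2 passed the test (limma adjusted p from 0.189 to 0.999), so for them Myd88 loss stays open beside passenger DNA. For called genes outside that region passenger DNA was not tested. Unequal sex was argued against, since with the Xist level as a covariate the effects were 0.97 times as large, and chance by 100 splits of the arrays, of which only the real one reached its 172 genes (highest other 20, the split of high against low Xist, 0 of whose genes were among the 172). Direct loss of Myd88 signalling, the biological explanation of the design, stays open as a hypothesis for the genes outside the region.

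The same calls were weighed against another share of neutrophils, which carry CD11b and which the beads would not remove, while a sort against Ly6G would. The median of 20 neutrophil markers was -0.201 at the bound set for it, so a changed share cannot be told apart from none. Their most abundant genes, S100a9 (12.75 in WT) and S100a8 (12.06), differed by -0.19 and -0.05, and 2 of the 27 genes of the list are also in another list. Of the 141 fallen genes 84 (0.596) fell beyond -0.64, the neutrophil median less its SD. These genes were called for their falls, which favours that, so neutrophils as the whole source cannot be told apart by it.

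The calls of population A were weighed against eosinophils, single WT arrays, sex and passenger DNA. Ccr3 read 7.3 in A_WT against 10.03, 9.48 and 9.56 in TNFR1-/-, Myd88 cKO and double KO, Siglecf 7.6 against 9.56, 9.43 and 9.41, Alox15 10.18 against 12.24, 11.87 and 11.93, Il5ra 5.62 against 7.23, 6.84 and 7.15, and the granule gene Prg2 5.9 against 7.18, 6.85 and 7.33. The granule gene Epx read 5.82 against 5.71, 5.72 and 5.72, near the medians of these arrays (5.37 to 5.5), where it decides nothing. A gate on Siglecf would remove eosinophils, and 1 of the 18 genes of their list is also in another list. Of the genes that rose in double KO a share of 0.629 was lower in A than in C of TNFR1-/- hosts. The bound of 0.5 set for this share before it was seen was wrong, because 0.497 of all tested genes are lower there, so eosinophils as the whole source cannot be told apart by it. For the cell cycle rises they were argued against, since the cell cycle median was -0.28 (SD 0.26) in TNFR1-/- against 0.67 in double KO, with eosinophil medians of 1.28 and 1.29. For the other rises they may contribute. RNA of EG7 cells or other T lymphocytes in the sort was not tested as a source of the calls in A. Cd3g read 8.44 in double KO of A against 6.69 in WT, 5.58 in TNFR1-/- and 6.74 in Myd88 cKO. Such RNA therefore stays open for the cell cycle rises and for the genes that exceeded the sum of the single effects.

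The A_WT arrays correlated with each other at 0.931, which does not say which of them deviates. For double KO, A_WT array 1 was argued against as the whole cause, since a share of 0.754 of the 950 genes was still called without it. Without A_WT array 2 the share was 0.521, with effects 0.958 times and standard errors 1.16 times as large, so that array cannot be told apart as a cause. For TNFR1-/- in A the shares of 108 genes were 0.963 without A_WT array 2, which argues against that array, and 0.037 without A_WT array 1. There the effects were 0.951 times and standard errors 1.17 times as large, so array 1 cannot be told apart.

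Without A_doubleKO array 1 only 1 of the 950 genes was called, and without A_doubleKO array 2 the number was 564. Without A_doubleKO array 1 effects were 0.898 and standard errors 1.25 times as large. No sign could reverse, as groups did not overlap. Passenger DNA around Tnfrsf1a was argued against for double KO in A, where 12 of 210 genes near it were called, a ratio of 0.994 to the share elsewhere (upper 95% limit of the odds ratio 1.78). The ratio of 1.14 over the 4 comparisons together rests mostly on those calls. For TNFR1-/- in A (0.732, 1 gene, upper limit 4.2), TNFR1-/- in C (ratio 0, 0 genes, upper limit 28.1) and double KO in C (3.17, 2 genes, Clec4d and Clec4e, Fisher exact p = 0.137) the genes are too few, so there it cannot be told apart.

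Unequal sex in double KO of C was argued against by effects 1.03 times as large with the Xist covariate, and by a ratio of 1 with the Y-linked Eif2s3y. Both are uncertain measures of sex, since some sorted arrays carried both transcripts and may hold RNA of mice of both sexes. In A the effects were 1.04 and 1.02 times as large for TNFR1-/- and double KO, with all 108 and 950 genes in the same direction. Standard errors were 1.27 and 1.08 times as large and 2 and 350 genes were called, so the calls ended because precision fell, not because the folds did. With Eif2s3y they were 1.04 and 0.999 times as large, with 111 and 781 genes called. Between WT and TNFR1-/- of A both transcripts split with genotype, so these fits rest there on slopes from other groups. Direct loss of Tnfrsf1a and Myd88 stays open.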

How the results depend on the processing

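The fits with the Xist or Eif2s3y level, within arrays of high or low Xist, with array weights and with crossed numbers were chosen after the data were seen. Over the alternatives 285 counts of calls were recomputed and 103 moved by over 1.5 times. Of 9136 values of 548 named genes, 7934 kept their side of the threshold, 1106 were no longer called, 96 became called and 0 called ones reversed. The cause was not tested except where a setting by its construction uses fewer arrays or a stricter rule.

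A minimum of 2-fold, where differences exactly at that bound depend on floating-point rounding, left 38 genes for Myd88-/-, 7050 between the EG7 WT arrays of both experiments, 560 for A against C, 215 for Myd88 cKO in A, 250 for double KO in A, 37 for double KO against TNFR1-/- and 56 against Myd88 cKO. Quantile normalization gave 5613 between the experiments, 413 for TNFR1-/- in A, 1 for Myd88 cKO in C and 3 for the A minus C difference of double KO. The EG7 arrays of both experiments gave 3000 for neuroblastoma, and all 16 arrays of the chip 4334 for neuroblastoma and 44 for Myd88-/-. Arrays with high Xist gave 79 for Myd88-/- and those with low Xist 12. No filter and the mean of probe sets each gave 0 for Myd88 cKO in C (limma, 636 at an unadjusted p under 0.05 in the planned comparison), the 60th percentile 178 for TNFR1-/- in A, and eBayes with trend and robust settings 1 for the A minus C difference of TNFR1-/-.

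The replicate numbers gave no common pairing, with correlations of same-numbered arrays from -0.05 to 0.21 in the tumour models, from -0.23 to 0.21 in the Myd88 experiment and from -0.5 to 0.37 in the sorted groups. Between A and C of one genotype they were 0.24 for WT, 0.03 for TNFR1-/-, 0.03 for Myd88 cKO and -0.2 for double KO, so that same-numbered arrays were not taken as pairs. A replicate block gave 0 for Myd88 cKO in C, 5 for non-additivity in A and 3 for the A minus C difference of double KO, and moved no other count by over 1.5 times. Crossed numbers as a random block gave 11 for that difference.

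The Xist level as a covariate gave 2 for TNFR1-/- in A, 115 for Myd88 cKO in A, 350 for double KO in A, 0 for Myd88 cKO in C, 1 for non-additivity in A, 63 for double KO against TNFR1-/-, 83 against Myd88 cKO and 3 for the A minus C difference of double KO. The Y-linked Eif2s3y as a covariate gave 235 for Myd88 cKO in A, 4 for Myd88 cKO in C and 64 for double KO against TNFR1-/-, and moved no other count by over 1.5 times. Array weights gave 1, 9 and 0 for TNFR1-/-, Myd88 cKO and double KO in A, 2 for non-additivity in A, 438 against TNFR1-/-, 351 against Myd88 cKO and 2 for the A minus C difference, and 301 for A against C. Only the 4 arrays compared gave 397 for A against C, 0 for double KO in A and 135 for double KO in C. With an estimated correlation 8 list tests were called, against 176, and 0 of the Myd88-/- gene sets in the sorted arrays, against 7.

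Leaving out 1 array at a time gave 704 to 2446 genes for neuroblastoma, 86 to 275 for Myd88-/-, 406 to 3429 for A against C, 2 to 1750 for TNFR1-/- in A, 8 to 1516 for Myd88 cKO in A, 2 to 2345 for double KO in A, 2 to 9 for TNFR1-/- in C, 0 for Myd88 cKO in C, 7 to 41 for double KO in C, 3 to 545 for non-additivity in A, 34 to 109 for double KO against TNFR1-/-, 52 to 142 against Myd88 cKO, and for the A minus C differences 0 to 295 for TNFR1-/-, 0 to 36 for Myd88 cKO and 2 to 97 for double KO. Where this leaves 1 array in a group, that array is assumed to vary like the other groups.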

Other observations

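The tests described here were planned, except the Xist covariate, which was chosen after the data were seen. In population C, the interferon lists were compared with WT in each genotype, and no member was called (0 in each). Type I interferon response genes had a median of 0.42 over 28 genes in TNFR1-/- hosts (camera adjusted p = 3.15e-11, adjusted p = 0.385 with an estimated correlation, fry adjusted p = 0.321, 2 higher adjusted over the list alone), with Oasl1 at 0.81 ± 0.17 (limma adjusted p = 0.162) and Usp18 at 0.81 ± 0.23. In Myd88 cKO hosts the median was -0.27 (adjusted p = 1.53e-06, adjusted p = 0.577 with an estimated correlation, fry adjusted p = 0.465), with Irf7 at -0.62 ± 0.19 and Rtp4 at -0.83 ± 0.27, and in double KO it was -0.16 (adjusted p = 0.138). With the Xist covariate the medians were 0.38, -0.36 and -0.17. Interferon-gamma response genes had a median of 0.13 over 25 genes in TNFR1-/- (adjusted p = 0.0433, adjusted p = 0.826 with an estimated correlation, fry adjusted p = 0.886), -0.34 in Myd88 cKO (adjusted p = 1.24e-06, adjusted p = 0.556 with an estimated correlation, fry adjusted p = 0.494) and -0.18 in double KO (adjusted p = 0.107), with 0 members adjusted over the list alone. The mean of the interferon-gamma list was 8.07 and 7.81 in WT, and the TNFR1-/- arrays lay on either side of these at 7.78 and 8.35. Since both list tests that allow for correlated genes called neither list, and the genotypes were not tested against each other here, no direction is claimed.

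The calls of neuroblastoma against EG7 were weighed against RNA of the tumour cells in the bead-enriched fraction, which carried no gate against them. The T lymphocyte and EG7 line markers had a median of -1.69, as RNA of EG7 cells would give, and Cd3d read 10.44 in EG7 against 4.85 in neuroblastoma, while Chgb read 3.58 against 10.84. None of the 25 and 24 genes of these marker lists is in another list (0 shared). Such RNA is therefore a candidate source for part of the calls, with 26 of the 37 tested members of both tumour lists called toward their own tumour and 1 called the other way. The lists are too short to bound how many of the 1850 calls such RNA explains, and a difference between the macrophages stays open. The 10 splits of these 6 arrays are too few for a share under 0.05, with 1850 genes in the real split and 0 in the highest other. Between the EG7 WT arrays of both experiments chance can be excluded, since 1 of 56 splits, the real one with 11390 genes, was as large and the highest other gave 1.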
